A study of Mus musculus with 10 samples.

How the data were processed

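The series holds RNA-seq of 10 low-input libraries of cells sorted from mouse liver by flow cytometry: 4 of hepatocyte-derived peripheral cholangiocytes (HpC), 3 of peripheral cholangiocytes (pC) and 3 of hepatocytes (H). Per the labels, HpC and H came from mice with the Alb-Cre transgene and floxed alleles of Rbpj and Hnf6, and pC from mice with the same floxed alleles and no Cre; Hnf6 is another name of the gene Onecut1. HpC and pC were sorted from nonparenchymal cells released by perfusion and further digestion, and H after perfusion, all straight into extraction buffer, and libraries were made with a low-input kit, per the labels' protocols. The mice were a mix of 3 strain backgrounds and were 119 to 151 days old, and reads were single-end and 50 bases long, per the labels. Libraries are named here by group and replicate number (HpC1 to HpC4, pC1 to pC3, H1 to H3). The ages given by the labels differ between all HpC libraries and between all pC libraries, so within those groups the libraries came from different mice. Of the HpC libraries only HpC4 has the age of an H library, that of H2 and H3. Only HpC4 may therefore share a mouse with H, and the labels do not say whether it does. H2 and H3 share an age, and the labels do not say whether they came from separate animals. For H the p-values may therefore measure only the spread between samples, which may be technical.

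The authors deposited 1 table per library with a TPM value, an abundance scaled to a fixed total, for each of 85276 Ensembl transcripts. The submitters' processing notes name kallisto and DESeq, with no versions or roles, and the mm10 genome build; which step DESeq served is not given in the sources used here. The deposited TPM of each library sums to the same total, so the values hold no sequencing depth. The numbers of reads are unknown, no counting error or detection limit can be given for any value, and no count-based test could be run. The choice of tests had assumed counts, with a named replacement should the values be normalised; that replacement, limma on log2 values, was used throughout, and DESeq was not used.

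Transcripts were joined to genes by Ensembl transcript identifier through the GENCODE M21 annotation, which is on mm10 and also gave the gene coordinates. Of the 85276 transcripts, 81927 matched and 3349 did not; unmatched transcripts held from 4.22% to 9.06% of the TPM of a library and were left out. Summing TPM over transcripts gave 29972 genes. Pseudogenes held 15.8% to 30.0% of the deposited TPM. Short single-end reads can be split between a gene and its near-identical copies, so values of ribosomal protein genes, major histocompatibility genes, haemoglobin genes, the Serpina1 and Serpina3 families, Cyp2a4 and Cyp2a5, Hamp2, Ugt2b1, and trypsin and elastase genes are uncertain as values of 1 gene.

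Genes with at least 1 TPM in at least 3 libraries were kept, which left 14765. TPM was rescaled between libraries by a trimmed mean of log ratios without precision weights, which left out 30% of the log ratios and 5% of the mean levels at each end; the resulting factors ran from 0.668 in HpC1 to 1.61 in HpC4 among HpC, from 1.53 to 1.59 in pC and from 0.499 to 0.585 in H. Values called scaled TPM were divided by these factors. Tests used log2(scaled TPM + 1), so that fold changes are on that scale and understate changes of low genes. Group means were compared by limma (version 3.58.1, in R 4.3.3) with a mean-dependent prior variance, in a single fit of all 10 libraries with 1 coefficient per group, and Benjamini-Hochberg adjustment over the 14765 genes at 5%. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

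Gene lists for liver cell identity and metabolism, biliary function, signalling pathways, stress, other liver cell types and RNA quality were fixed before the data were examined, as were the main tests and most of the alternatives. Lists with at least 5 tested members, 31 in number, were tested against all other genes with limma's camera. The tests used a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again a correlation estimated per list. The second form also has far fewer degrees of freedom and so less power, whatever the correlation. A list that misses the threshold only in that form is therefore not shown to owe its call to correlation between genes, nor to be unchanged. Counts of list members past the threshold are given over all genes and adjusted over the list alone. A list score is the mean log2 value of its tested members, compared by a two-sided exact permutation test over the 35 splits of 4 and 3 libraries, whose smallest possible p is 0.0286. The position of a library between hepatocytes and cholangiocytes was the least-squares slope over genes differing at least 4-fold between H and pC, on axes that the placed pC and H libraries did not help to define.

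Genes named in the text were chosen by a rule set beforehand. It took both floxed genes and 9 marker genes whatever their values, the 5 largest rises and 5 largest falls among called genes with a mean log2 level of at least 5 and no overlap between the libraries of the groups, up to 3 called members of each core list and the leading member of each other list. Most named genes were thus chosen for being called or for a small p in the same data. How many of them pass or stay called therefore says little about other genes. Not every gene picked by the rule is printed. Predicted genes, mitochondrial, immunoglobulin, major urinary protein and histone genes were left out of the largest changes. Other members of a list, transcripts of other organs and genes close to absent from a group are named to show what a count holds, and were chosen after their values were seen.

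The fitting steps were tested on simulated data in which known genes were changed by known amounts, with the residual spread of the real genes. For HpC against pC, 44% of genes changed by 1 on the log2 scale and 89% of those changed by 2 were recovered among 14437 genes, and 3.62% of calls were unchanged genes. For HpC against H the recovered shares were 42% and 78%, and for pC against H 40% and 82%. Alternatives were another scaling, TPM as deposited, other pseudocounts, no filter, only the libraries of both groups compared, the replicate number as a block, age as a covariate, array weights, protein-coding nuclear genes only, and leaving out each library. For calls of genes and lists, TPM as deposited, the pseudocounts, the array weights, the protein-coding set and the fit without both HpC libraries that held transcripts of other organs were chosen after seeing the data. A count-model Wald test, voom with sample quality weights and an average-length offset need counts or effective lengths and were not run.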

Results

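RNA-seq of sorted mouse liver cells covered 4 libraries of hepatocyte-derived peripheral cholangiocytes (HpC), 3 of peripheral cholangiocytes (pC) and 3 of hepatocytes (H). Cholangiocytes are the epithelial cells that line bile ducts, and peripheral ones line the small ducts inside the liver. HpC came from mice in which Cre, driven by the albumin promoter, acts on floxed Rbpj, the DNA-binding effector of Notch signalling. It also acts on floxed Hnf6 (Onecut1), a transcription factor needed for bile duct formation. The series title states that a biliary system can form anew from hepatocytes that change identity through TGF-beta. The comparisons below ask how far such cells differ from ordinary cholangiocytes and from hepatocytes. Libraries had between 10232 (H2) and 14489 (pC3) genes at 1 TPM or more. The number of reads is unknown. Across genes, log2 values of library pairs correlated at 0.983 to 0.986 within H, 0.972 to 0.981 within pC, and 0.911 to 0.975 within HpC. They were 0.923 to 0.970 between HpC and pC and 0.759 to 0.820 between H and either cholangiocyte group. These correlations are across genes, which are not independent replicates. Genes of the mitochondrial genome took 22.6% to 26.1% of the TPM in H, 5.78% in HpC1 and 10.5% to 14.4% in the other libraries.

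Both HpC1 and HpC2 held transcripts of other organs at high levels. In HpC1, 79 genes were over 10 times higher than in every other library and together made up 32.1% of its TPM. All 15 pancreatic digestive enzymes examined were among them and took 20.5% of the TPM of HpC1, against 0.203% in pC3, 0.0304% in HpC3 and less in the others. The elastase gene Cela2a alone stood at 29691 deposited TPM. In HpC2, 156 genes were over 10 times higher than elsewhere and made up 6.28% of its TPM. Among them were 13 of 14 keratins and cornified envelope genes of stratified squamous epithelium, which took 4.74% of the TPM. The squamous keratin Krt13 stood at 36853 deposited TPM and Trp63, a master regulator of squamous epithelium, at 78.0. The other 8 libraries had at most 3 such single-library genes each. Counts of changed genes are therefore also given without both libraries.

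**Figure D1:**
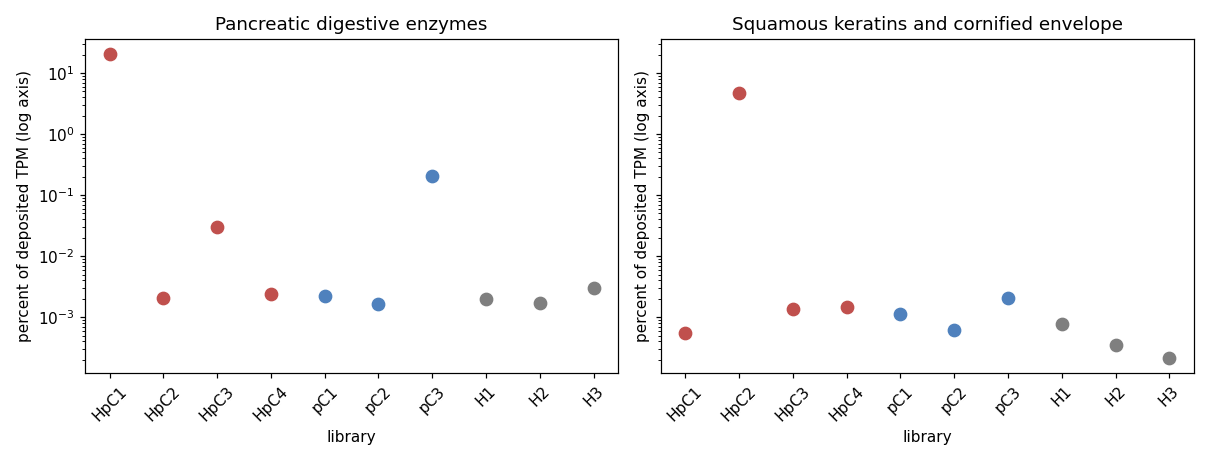
Percent of deposited TPM (log axis) taken by 15 pancreatic digestive enzyme genes (left) and by 14 squamous keratin and cornified envelope genes (right), 1 point per library, coloured by group (red HpC, blue pC, grey H). The pancreatic share was 20.5% in HpC1 and at most 0.203% elsewhere, and the squamous share was 4.74% in HpC2 and at most 0.00203% elsewhere.

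The floxed genes were examined first. Rbpj (ENSMUSG00000039191, mm10 chromosome 5, 53466152 to 53657362, plus strand) stood at 4.23, 4.09, 4.60 and 6.24 scaled TPM in HpC1 to HpC4, and at 5.51, 5.85 and 6.82 in pC1 to pC3. In H1 to H3 it stood at 1.59, 1.26 and 1.20. HpC and pC differed by -0.30 ± 0.17 (SE) on the log2 scale (limma adjusted p = 0.398), and both were above H, by 1.29 ± 0.17 (adjusted p = 8.06e-05) and 1.59 ± 0.18 (adjusted p = 3.08e-05). Onecut1 (ENSMUSG00000043013, chromosome 9, 74861921 to 74891781, plus strand) averaged 32.0 ± 12.2 scaled TPM (SD, n = 4) in HpC, 72.6 ± 9.44 (n = 3) in pC and 81 ± 32.2 (n = 3) in H. Its difference between HpC and pC, -1.22 ± 0.34, did not pass (limma adjusted p = 0.0805), though it did without HpC4 (adjusted p = 0.0435). That between HpC and H, -1.30 ± 0.34, passed (adjusted p = 0.00768), except on TPM as deposited. A floxed allele loses part of the gene only, and the values sum whole transcripts, so these levels do not check the deletion.

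Hepatocyte-derived cholangiocytes differed from ordinary peripheral cholangiocytes in 671 of 14765 genes, 294 higher and 377 lower (limma, 5% false discovery rate). The Notch target Hes1 fell from 538 ± 235 scaled TPM in pC (SD, n = 3) to 62.5 ± 7.95 in HpC (n = 4), and Spp1, which encodes osteopontin, from 4223 ± 178 to 953 ± 325. Pigr, the receptor that carries immunoglobulin A into bile, fell from 356 ± 123 to 18.9 ± 17.5. In the other direction, the basement membrane gene Nid1 rose from 0.622 ± 0.165 to 16.2 ± 4.56, and the squamous cornified envelope gene Sprr1a from 38.9 ± 17.4 to 503 ± 267. Several plasma protein genes of hepatocytes were also higher in HpC, while genes of antigen presentation were lower.

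Among genes with a mean log2 level of at least 5 and no overlap between groups, the largest falls in HpC were those of Pigr, by -4.54 ± 0.60 on the log2 scale (SE; limma adjusted p = 0.00298), and Hes1 (-2.99 ± 0.31, adjusted p = 0.000924). Next came the class II histocompatibility gene H2-Ab1 (-2.77 ± 0.42, adjusted p = 0.00521), Rgs2, a regulator of G protein signalling (-2.61 ± 0.25, adjusted p = 0.000626), and H2-Eb1 (-2.54 ± 0.42, adjusted p = 0.00811). Hes1 (ENSMUSG00000022528) lies on chromosome 16 at 30064384 to 30067796 and Pigr (ENSMUSG00000026417) on chromosome 1 at 130826684 to 130852249, both on the plus strand. The largest rises under the same limits were those of Sprr1a (3.54 ± 0.51, limma adjusted p = 0.00379), Hp, encoding haptoglobin (3.24 ± 0.50, adjusted p = 0.00571), and Trf, encoding transferrin (2.85 ± 0.49, adjusted p = 0.0102). Next came Gc, encoding the vitamin D-binding protein (2.59 ± 0.43, adjusted p = 0.00811), and Serpina1a, an alpha-1-antitrypsin gene (2.45 ± 0.47, adjusted p = 0.0165). Without HpC1 and HpC2, Trf (2.53, adjusted p = 0.0554) and Serpina1a (2.24, adjusted p = 0.0924) no longer passed in limma with fewer libraries, at folds close to those above, while Sprr1a, Hp and Gc did.

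**Figure D2:**
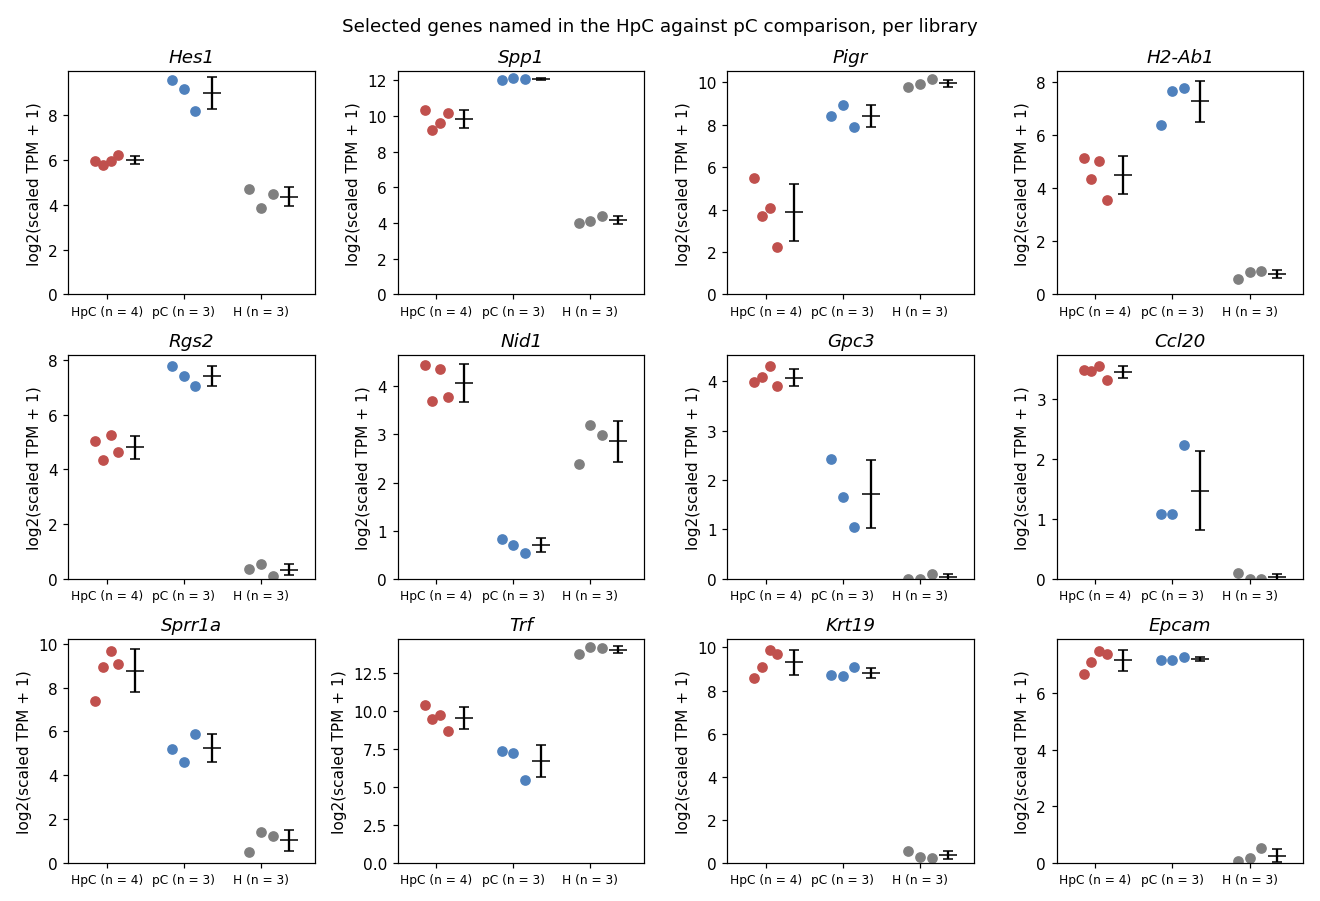
Level of 12 genes as log2(scaled TPM + 1), 1 point per library, in HpC (red, n = 4), pC (blue, n = 3) and H (grey, n = 3); black marks give the mean and SD of each group. Hes1, Spp1, Pigr, H2-Ab1 and Rgs2 lay lower in every HpC library than in every pC library, and Nid1, Gpc3, Ccl20, Sprr1a and Trf higher, while Krt19 and Epcam overlapped.

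Markers of duct identity were mixed. Of 19 genes on the cholangiocyte identity list, none rose, 3 fell and 16 did not pass over all genes; adjusted over the list alone, 1 was higher and 7 lower. Its limma camera test did not pass (adjusted p = 0.112; adjusted p = 0.827 with an estimated correlation). The list did pass as lower without HpC3 (adjusted p = 0.0325), HpC4 (0.0278) or pC2 (0.0216). Without HpC1 and HpC2 together its mean went from -0.24 to 0.03 (adjusted p = 0.964). Epcam, a surface marker of duct cells, was at 145 ± 34.9 scaled TPM in HpC and 147 ± 6.45 in pC. The duct keratins Krt19 (673 ± 255 against 456 ± 72.6; limma adjusted p = 0.422) and Krt7 (120 ± 29.0 against 66.4 ± 13.5; adjusted p = 0.0509) did not pass, but both did without HpC1 and HpC2 (adjusted p = 0.0233 and 0.0193), and Krt7 also without HpC1 or HpC2 alone. The duct regulator Sox9 (-0.96 ± 0.29, adjusted p = 0.107) and the chloride channel gene Cftr (adjusted p = 0.108) did not pass either. Those that fell included Spp1 (-2.21 ± 0.26, limma adjusted p = 0.00149) and Prom1 (-0.85 ± 0.21, adjusted p = 0.0460). The Prom1 call ended without any single library except HpC4 and H2 (highest adjusted p = 0.183).

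Biliary secretion and transport genes moved in both directions: 3 of 14 were higher, 2 lower and 9 did not pass (3 and 5 adjusted over the list alone). The higher ones were the bile acid transporter Slc10a2 (1.01 ± 0.19, limma adjusted p = 0.0156), the water channel Aqp1 and the chloride transporter Slc12a2. The lower ones were Pigr and Atp1b1, a subunit of the sodium pump (-1.07 ± 0.16, adjusted p = 0.00506). The Slc10a2 call ended without pC1 (adjusted p = 0.0655) or pC2 (adjusted p = 0.0908). The Slc12a2 call ended without pC2 (adjusted p = 0.0591) and the Aqp1 call without HpC3 or any single pC library (highest adjusted p = 0.108). The list's median log2 fold change was 0.12, its mean -0.27 and its camera direction down (adjusted p = 0.971; adjusted p = 0.969 with an estimated correlation). None of 15 primary cilium genes passed singly, over all genes or adjusted over the list alone, but the list lay lower in HpC (median -0.35, camera adjusted p = 0.0193; adjusted p = 0.710 with an estimated correlation). That call ended without HpC1 (adjusted p = 0.0667) and without HpC2 (adjusted p = 0.155), and the mean went from -0.29 to -0.08 without both (adjusted p = 0.818). It ended too on TPM as deposited and with array weights. Epithelial junction and polarity genes showed no called member among 13 (1 higher adjusted over the list alone), with a median of -0.04, a mean of 0.05 and an upward camera direction (adjusted p = 0.971; adjusted p = 0.980 with an estimated correlation).

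Signalling lists did not move as a whole. Of 21 Notch pathway genes 1 was higher, 3 lower and 17 did not pass (2 and 3 adjusted over the list alone). The median was 0.16, the mean -0.06 and the camera direction down (adjusted p = 0.971; adjusted p = 0.980 with an estimated correlation). The lower ones were Hes1, the Notch target Hey1 (-0.79 ± 0.16, limma adjusted p = 0.0226) and the receptor gene Notch2. The higher one was Lfng, which encodes a glycosyltransferase acting on Notch (1.34 ± 0.30, adjusted p = 0.0319). Hey1 lost its call without HpC3 or any single pC library (highest adjusted p = 0.115), and Notch2 and Lfng without HpC3, any single pC or any single H library (highest adjusted p = 0.130 and 0.120). Of 23 TGF-beta pathway genes, 3 were higher, none lower and 20 did not pass (6 and 3 adjusted over the list alone). The list had a median of -0.13, a mean of 0.27 and an upward camera direction (adjusted p = 0.442; adjusted p = 0.844 with an estimated correlation). Among them were Ltbp2, which encodes a TGF-beta binding protein (2.58 ± 0.46, limma adjusted p = 0.0125), and Tgfbi (1.46 ± 0.34, adjusted p = 0.0367). Ltbp2 lost its call without pC2 (adjusted p = 0.0601) and Tgfbi without any single library except HpC4 and H1 (highest adjusted p = 0.131). In the Hippo-YAP list of 20, the receptor kinase gene Axl was higher (2.02 ± 0.32, adjusted p = 0.00616), the YAP target Ankrd1 lower (-1.44 ± 0.34, adjusted p = 0.0402) and 18 did not pass (1 and 1 adjusted over the list alone; camera adjusted p = 0.818; adjusted p = 0.962 with an estimated correlation). The Axl call ended on TPM as deposited (limma adjusted p = 0.067). The Ankrd1 call ended without any single library except HpC4 and pC2 (highest adjusted p = 0.160).

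Matrix and mesenchymal genes lay higher in HpC. On the epithelial-mesenchymal transition list 4 of 7 were higher, none lower and 3 did not pass (5 and none adjusted over the list alone). The camera adjusted p was 9.28e-06, and adjusted p = 0.0454 with an estimated correlation, the only list of this comparison to pass both ways. They were the N-cadherin gene Cdh2 (2.10 ± 0.29, limma adjusted p = 0.00335), S100a6, the intermediate filament gene Vim and the repressor gene Zeb2. Cdh2 is also a hepatocyte cadherin and stood at 38.8 ± 2.58 scaled TPM in H. Vim and Zeb2 lost their calls without HpC3 or any single pC library (highest adjusted p = 0.0952 and 0.0838). Of 17 basement membrane and integrin genes 3 rose (Nid1, at 3.38 ± 0.25, adjusted p = 0.000165, Itga2 and Lamb1), Lamb2 fell and 13 did not pass (5 and 1 adjusted over the list alone; camera adjusted p = 0.00165; adjusted p = 0.710 with an estimated correlation). Lamb1 lost its call without HpC3, HpC4, pC1 or pC2 (highest adjusted p = 0.141) and Lamb2 without any single library except pC3 (highest adjusted p = 0.188). Markers of other cell types of the liver lay higher beside these. Of 14 stellate cell and fibroblast markers 1 passed, the collagen gene Col3a1 (7.67 ± 2.99 against 2.68 ± 0.189 scaled TPM, adjusted p = 0.0219), or 4 higher and 1 lower adjusted over the list alone. The median was 0.61 (camera adjusted p = 0.00248; adjusted p = 0.710 with an estimated correlation). Col3a1 lost its call without HpC3 or any single pC library (highest adjusted p = 0.102). Of 7 mesothelial markers, 3 were higher (Upk1b, at 1.69 ± 0.19, adjusted p = 0.00122, Msln and Wt1), 1 lower (Gpm6a) and 3 did not pass (6 and 1 adjusted over the list alone; camera adjusted p = 0.00199; adjusted p = 0.151 with an estimated correlation). Msln lost its call without HpC3, pC1 or pC2 (highest adjusted p = 0.118), Wt1 without HpC3, HpC4, H2, H3 or any single pC library (0.140), and Gpm6a without pC1 or pC2 (0.0774).

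Some plasma protein genes of hepatocytes were higher in HpC than in pC but stayed far under their level in H. On the list of 22 secreted proteins 5 were higher, 1 lower and 16 did not pass (9 and 1 adjusted over the list alone). The median was 1.29 and the camera adjusted p 6.10e-07, or adjusted p = 0.710 with an estimated correlation. They were Hp, Trf, the apolipoprotein gene Apob (2.40 ± 0.45, limma adjusted p = 0.0148) and the complement genes C3 and Cfb, while Ambp fell. Apob lost its call without HpC1 and HpC2 together, with fewer libraries and a fold of 2.23 (adjusted p = 0.0688), Cfb and Ambp without pC1 or pC2 (highest adjusted p = 0.0908 and 0.107), and C3 without any single library except HpC2 and pC3 (0.165). Trf stood at 812 ± 386 scaled TPM in HpC, 118.6 ± 65.8 in pC and 16755 ± 2688 in H. Albumin (Alb), which did not pass (limma adjusted p = 0.0866), stood at 3607 ± 1159, 1534 ± 678 and 54662 ± 3994. The list score was 6.56 ± 1.02 in HpC and 5.18 ± 1.01 in pC, a difference of 1.38 (exact permutation p = 0.171; adjusted p = 0.448 over the list scores). Among HpC the score was highest in HpC1, 7.57, and lowest in HpC4, 5.23. On the bile acid synthesis and transport list 1 of 14 was higher, the canalicular exporter Abcc2 (2.04 ± 0.29, limma adjusted p = 0.00360), and 13 did not pass (4 and none adjusted over the list alone; camera adjusted p = 0.00289; adjusted p = 0.763 with an estimated correlation). The list's call ended without HpC1 (adjusted p = 0.0568), without pC3 (adjusted p = 0.0902) and without HpC1 and HpC2 together (0.163), where the mean went from 0.72 to 0.40.

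Other liver metabolism and regulator lists did not pass. None of 14 urea cycle and amino acid genes (camera adjusted p = 0.252), 14 xenobiotic genes (adjusted p = 0.127) or 15 fatty acid genes (adjusted p = 0.971; median -0.04, mean 0.02, direction down) was called, and adjusted over the list alone none was either. With an estimated correlation these gave adjusted p = 0.844, 0.827 and 0.980. Without HpC4 the urea cycle and xenobiotic lists passed as higher (camera adjusted p = 0.00903 and 0.00276), and the xenobiotic list also without pC2 (0.0216). Leaving out other libraries moved them the other way: the urea cycle mean went from 0.33 to -0.11 without HpC1 and -0.22 without HpC1 and HpC2 together, and the xenobiotic mean from 0.59 to 0.25 without pC3 and 0.07 without HpC1 and HpC2. Of 12 glucose genes Pklr was higher and the glucose transporter gene Slc2a2 lower (-0.87 ± 0.16, limma adjusted p = 0.0148), and the list gave a camera adjusted p of 0.707. Slc2a2 lost its call without pC1 (adjusted p = 0.0741) or pC2 (adjusted p = 0.0859). Pklr lost it without any single library except HpC2 (highest adjusted p = 0.213). Among 16 liver-enriched transcription factors, Prox1 (-1.81 ± 0.27, adjusted p = 0.00525) and Nr5a2 (-1.14 ± 0.24, adjusted p = 0.0246) were lower and 14 did not pass (none higher and 3 lower adjusted over the list alone; camera adjusted p = 0.438; adjusted p = 0.844 with an estimated correlation). Nr5a2 lost its call without HpC3 (adjusted p = 0.0688), pC1 (0.104) or pC2 (0.118). Hnf4a, a central hepatocyte regulator, stood at 66.7 ± 16.4 scaled TPM in HpC, 49.3 ± 8.61 in pC and 346 ± 23.1 in H (HpC against pC adjusted p = 0.346). Of 10 Wnt target and pericentral genes none passed (1 higher adjusted over the list alone; camera adjusted p = 0.167).

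Immune and stress genes were lower in part. Of 9 antigen presentation genes 7 were lower and 2 did not pass, and all 9 were lower adjusted over the list alone (median -2.04, camera adjusted p = 1.12e-10; adjusted p = 0.151 with an estimated correlation). H2-Ab1 averaged 23.9 ± 10.8 scaled TPM in HpC and 168 ± 74.2 in pC. Ciita, the master regulator of class II genes, averaged 0.550 ± 0.117 and 5.90 ± 3.49 (-2.04 ± 0.28, limma adjusted p = 0.00323). Without any single pC library Ciita missed the low-value filter and was not tested. Of the others, Cd74, Tap1 and H2-Eb1 kept their calls without any single library. H2-Aa lost its call without pC2 (adjusted p = 0.0524) and H2-K1 without any single library except pC1 (highest adjusted p = 0.102). Of 12 interferon response genes 3 were lower, Gbp2 and Psmb8 among them, and 9 did not pass (none higher and 3 lower adjusted over the list alone; camera adjusted p = 0.00552; adjusted p = 0.710 with an estimated correlation). Gbp2 lost its call without any single library except pC1, H1 and H2 (highest adjusted p = 0.130). The list lost it without HpC2 (adjusted p = 0.0717) or pC3 (adjusted p = 0.0902). Immediate early genes lay lower, with 1 of 15 called, Ier2 (-1.01 ± 0.18, adjusted p = 0.0123), and 14 not (none higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00398; adjusted p = 0.710 with an estimated correlation). Ier2 lost its call without pC1 (adjusted p = 0.0623) or pC2 (adjusted p = 0.0736) and the list without HpC1 (adjusted p = 0.0521). Without HpC1 and HpC2 together the list mean went from -0.47 to -0.24 (adjusted p = 0.319). Among 17 chemokine and inflammatory genes, Ccl2 (3.50 ± 0.77, adjusted p = 0.0307) and Ccl20 (1.98 ± 0.26, adjusted p = 0.00284) were higher and 15 did not pass (3 and none adjusted over the list alone; camera adjusted p = 0.0644; adjusted p = 0.827 with an estimated correlation). Ccl2 lost its call without any single library except HpC4 and pC3 (highest adjusted p = 0.127). The list passed without HpC1, HpC2 or pC3, and without HpC1 and HpC2 together (adjusted p = 0.000192), but its mean went from 0.56 to 0.24 without pC1.

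Of the remaining lists, cell cycle genes had 1 called member of 17, Ccne1 (0.92 ± 0.21, limma adjusted p = 0.0392; lost without any single library except pC2, highest adjusted p = 0.160), with a camera adjusted p of 0.111, or adjusted p = 0.827 with an estimated correlation. That list passed as higher without HpC4 (adjusted p = 0.0222) or pC1 (0.0206), but its mean went from 0.38 to 0.05 without HpC2 (0.916). The p53 and senescence list (0 of 8, or 2 higher adjusted over the list alone, adjusted p = 0.187) and the ER stress list (0 of 10, adjusted p = 0.257) did not pass. Gpc3, an oncofetal glypican and the only tested member of 9 fetal liver genes, was higher (16.0 ± 2.13 against 2.55 ± 1.70 scaled TPM; 2.36 ± 0.28, limma adjusted p = 0.00151). Markers of macrophages (0 of 10, camera adjusted p = 0.447), liver endothelium (0 of 12, adjusted p = 0.426), erythroid cells (0 of 5, adjusted p = 0.268) and lymphocytes (0 of 3 tested) had no called member, and none of 9 neutrophil and dendritic cell markers reached the filter. With an estimated correlation the macrophage and erythroid lists gave adjusted p = 0.880 and 0.834. The macrophage list passed as lower without HpC3 (adjusted p = 0.0320), but its mean went from -0.21 to -0.03 without HpC2. The erythroid list passed as higher without HpC4 (0.0196), but its mean went from 0.58 to 0.12 without HpC1. Ribosomal protein genes (0 of 16, mean 0.47, camera adjusted p = 0.00257; adjusted p = 0.763 with an estimated correlation) and respiratory chain genes (0 of 15, mean 0.29, adjusted p = 0.0167; adjusted p = 0.827 with an estimated correlation) lay higher as lists. The ribosomal call ended without HpC2 (adjusted p = 0.0715), and its mean fell to -0.02 without HpC1 and HpC2 together. The respiratory chain call ended without HpC1 (adjusted p = 0.0613), HpC2 (0.169) or pC3 (0.180), and its mean was -0.13 on TPM as deposited.

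The count of changed genes depended on the libraries and the scaling. Without HpC1 and HpC2 it was 316 higher and 243 lower, with 386 of the 671 genes kept. It was 138 and 133 without pC2, 159 and 171 without pC1, 191 and 224 without HpC3, and 219 and 224 without pC3. It was 202 and 191 in only the libraries of both groups, and 831 and 966 with array weights. On TPM as deposited 26.1% of the 552 calls were higher against 43.8% after scaling, with the median of all genes shifted to -0.36. Genotype differs with cell origin here and cannot be separated from it.

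Against hepatocytes of the same genotype, hepatocyte-derived cholangiocytes had lost most hepatocyte expression and held a duct cell profile. Krt19 stood at 673 ± 255 scaled TPM in HpC (SD, n = 4) and 0.285 ± 0.162 in H (n = 3), Epcam at 145 ± 34.9 and 0.204 ± 0.204, and Sox9 at 102 ± 28.7 and 4.60 ± 1.59. Alb stood at 3607 ± 1159 and 54662 ± 3994, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 6.95 ± 6.40 and 826 ± 133. Of 14765 genes 4528 were higher in HpC and 4314 lower (limma, 5% false discovery rate). All 68 genes named by rule passed, and 66 of them did so in every alternative. Most were picked for being called or for the smallest p of a list, so that they passed follows largely from the choice. The exceptions were Onecut1, which did not pass on TPM as deposited, and the Wnt target Notum, which was not tested without any single H library.

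Under the same limits the largest rises were those of Krt19 (8.96 ± 0.29 on the log2 scale, SE; limma adjusted p = 2.69e-08), the YAP target Ccn2 (8.21 ± 0.24, adjusted p = 2.69e-08), and Sprr1a (7.73 ± 0.51, adjusted p = 7.17e-07). Next came Igfbp7 (7.27 ± 0.17, adjusted p = 6.69e-09) and the ezrin gene Ezr (7.10 ± 0.24, adjusted p = 3.55e-08). Large falls were those of the hepcidin gene Hamp2 (-8.68 ± 0.76, adjusted p = 4.87e-06), and the apolipoprotein gene Apoa4 (-7.95 ± 0.96, adjusted p = 4.89e-05). Others were Apoa2 (-7.49 ± 1.05, adjusted p = 0.000146), Serpina3k (-7.45 ± 1.22, adjusted p = 0.000427) and the hepatokine gene Fgl1 (-7.40 ± 0.63, adjusted p = 3.94e-06). All 22 secreted protein genes, 14 bile acid genes, 14 urea cycle and amino acid genes, 14 xenobiotic genes, 12 glucose genes and 15 fatty acid genes were lower, as they were adjusted over the list alone. Their camera adjusted p values ran from 4.34e-09 (secreted proteins) to 1.51e-06 (xenobiotic genes), and with an estimated correlation from adjusted p = 0.116 to 0.231. Of 16 liver-enriched transcription factors 14 were lower, among them Nr1i3, a xenobiotic receptor (-5.88 ± 0.39, limma adjusted p = 8.14e-07), Creb3l3 and Hnf4a (-2.39 ± 0.21, adjusted p = 4.79e-06). Foxa1 was higher and 1 did not pass (camera adjusted p = 9.14e-05; adjusted p = 0.205 with an estimated correlation).

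All 19 cholangiocyte identity genes were higher in HpC than in H, also adjusted over the list alone (median 5.66, camera adjusted p = 5.14e-12; adjusted p = 0.116 with an estimated correlation). Among them were Spp1 (5.66 ± 0.26, limma adjusted p = 1.04e-07) and Krt7 (6.56 ± 0.21, adjusted p = 2.69e-08). Biliary secretion genes were higher in 10 of 14 and lower in 3, with the chloride channel genes Ano1 and Cftr among the higher and Pigr the lowest (-6.09 ± 0.60, adjusted p = 1.18e-05). Of 15 cilium genes 12 were higher and 1 lower. Of 21 Notch pathway genes 14 were higher and 1 lower, led by the ligand gene Jag1 (5.89 ± 0.24, adjusted p = 6.31e-08). Of 23 TGF-beta pathway genes 19 were higher and 1 lower, including the integrin gene Itgb6 (5.44 ± 0.29, adjusted p = 2.19e-07), the ligand gene Tgfb2 (4.39 ± 0.37, adjusted p = 4.05e-06) and Ltbp2 (4.41 ± 0.46, adjusted p = 1.81e-05). Of 20 Hippo-YAP genes 16 were higher and none lower, among them Ccn2 and Ankrd1 (7.12 ± 0.34, adjusted p = 1.23e-07). Of 17 chemokine and inflammatory genes 15 were higher and 1 lower. The camera tests of these 6 lists passed (adjusted p from 3.11e-06 for Hippo-YAP to 0.0149 for secretion), and none did with an estimated correlation (adjusted p from 0.116 to 0.236). The estimated correlations of the Notch and secretion lists, 0.00173 and -0.0261, were under the preset 0.01. Their unadjusted camera p still rose, from 0.000958 to 0.00926 and from 0.011 to 0.031, so that rise is not due to correlation between their genes. The secretion call ended on TPM as deposited (camera adjusted p = 0.107).

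Immediate early and heat shock genes were higher in HpC than in H in 14 of 15 (camera adjusted p = 7.24e-06; adjusted p = 0.205 with an estimated correlation), and the sorts differed in digestion. Basement membrane genes were higher in 16 of 17, junction genes in 10 of 13 and cell cycle genes in 12 of 17. These lists did not pass with an estimated correlation (camera adjusted p = 0.116, 0.227 and 0.4). Wnt target and pericentral genes were lower in 8 of 10, and respiratory chain genes in 15 of 15 (camera adjusted p = 1.51e-06; adjusted p = 0.236 with an estimated correlation). Markers of other cell types were higher in HpC: 14 of 14 stellate, 7 of 10 macrophage, 8 of 12 endothelial and 6 of 7 mesothelial markers. With an estimated correlation these lists did not pass (camera adjusted p = 0.236, 0.373, 0.369 and 0.116), nor did the Wnt list (0.116). The macrophage and endothelial calls ended on TPM as deposited, and the endothelial one also in only the libraries of both groups. The macrophage receptor gene Csf1r stood at 16.6 ± 6.44 scaled TPM in HpC. Lists that did not pass were the epithelial-mesenchymal one (3 higher, 2 lower; median -0.70, mean 0.92, direction up; camera adjusted p = 0.780), ER stress (median -0.03, mean 0.03, direction down; adjusted p = 0.896). Nor did interferon response (adjusted p = 0.411), antigen presentation (4 of 9 higher; adjusted p = 0.182), p53 and senescence, erythroid and ribosomal genes. On TPM as deposited 83.3% of calls were higher (7553 higher, 1519 lower) against 51.2% after scaling, with the median of all genes at 0.87 rather than 0.08. Directions here are relative to the scaling. Without HpC1 and HpC2, 9057 genes were called, 8123 of them among the 8842.

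Ordinary peripheral cholangiocytes showed the contrast between duct cells and hepatocytes that the study's other groups can be set against. Spp1 stood at 4223 ± 178 scaled TPM in pC and 17.1 ± 2.57 in H (SD, n = 3 each), Hes1 at 538 ± 235 and 19.9 ± 5.74, and Ankrd1 at 676 ± 273 and 0.710 ± 0.208. Alb stood at 1534 ± 678 in pC and 54662 ± 3994 in H. Of 14765 genes 4590 were higher in pC and 4216 lower (limma, 5% false discovery rate). Of the 64 genes named by rule 61 passed, most of them picked for being called or for the smallest p of a list. Genotype, Cre and isolation differ between these groups together with cell type.

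Under these limits the largest rises in pC were those of Ankrd1 (8.55 ± 0.36 on the log2 scale, SE; limma adjusted p = 6.99e-08), Spp1 (7.87 ± 0.28, adjusted p = 5.30e-08), and the immediate early gene Fosb (7.33 ± 0.31, adjusted p = 6.99e-08). Next came the invariant chain gene Cd74 (6.67 ± 0.36, adjusted p = 2.47e-07) and Ezr (6.63 ± 0.26, adjusted p = 5.68e-08). Large falls were those of the cytochrome genes Cyp2a4 (-8.91 ± 0.90, adjusted p = 1.44e-05) and Cyp2a5 (-8.62 ± 0.85, adjusted p = 1.24e-05). Others were Cyp7a1 (-8.60 ± 1.01, adjusted p = 4.35e-05), the kininogen gene Kng1 (-8.45 ± 0.89, adjusted p = 1.94e-05) and Slc27a2, a fatty acid transport gene (-8.45 ± 0.82, adjusted p = 1.03e-05). All 19 cholangiocyte identity genes were higher (camera adjusted p = 5.03e-12; adjusted p = 0.142 with an estimated correlation). All 22 secreted protein, 14 bile acid, 14 urea cycle, 14 xenobiotic and 15 fatty acid genes and 11 of 12 glucose genes were lower. Hes1 (4.62 ± 0.33, limma adjusted p = 1.36e-06) and Jag1 (5.15 ± 0.26, adjusted p = 1.57e-07) led the Notch list, of which 12 of 21 were higher and 2 lower (camera adjusted p = 0.00328; adjusted p = 0.142 with an estimated correlation). Of 23 TGF-beta genes 18 were higher and of 20 Hippo-YAP genes 16. Antigen presentation genes were higher in 8 of 9, with only B2m lower (median 2.50, camera adjusted p = 0.00247, or 0.282 with an estimated correlation), led by Cd74. Macrophage markers were higher in pC than in H as well (9 of 10), and their part in this rise was not tested. Onecut1 did not pass (-0.08 ± 0.37, adjusted p = 0.867); on TPM as deposited it was 1.46.

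Several lists of other cell types passed as higher in pC. Macrophage markers were higher in 9 of 10 (camera adjusted p = 0.00633, or 0.373 with an estimated correlation) and stellate markers in 6 of 14 (adjusted p = 0.0049, or 0.376). Both of these calls ended on TPM as deposited. Mesothelial markers (5 of 7 higher, camera adjusted p = 0.0465, or 0.215 with an estimated correlation) and endothelial markers (8 of 12 higher, adjusted p = 0.0426, or 0.447) passed too. The mesothelial call ended without HpC2, pC1, H2 or H3 (highest adjusted p = 0.0720) and the endothelial one without HpC2, HpC4, pC2, pC3, H2 or H3 (highest adjusted p = 0.0830). The mesothelial and endothelial calls also ended with the other scaling, on TPM as deposited and with a pseudocount of 5. Array weights ended the mesothelial call too, and leaving out HpC1 and HpC2 together the endothelial one. On TPM as deposited 88.2% of calls were higher (9361 higher, 1255 lower) against 52.1% after scaling, with the median of all genes at 1.20 rather than 0.11. Sdha, a respiratory chain gene that fell by 2.19 after scaling, no longer passed (-0.63).

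Both cholangiocyte groups were then set side by side against the same hepatocytes. Of the genes called against H, 7652 were called in the same direction in HpC and pC, 3868 higher and 3784 lower, and 9 in opposite directions. Independent lists of these sizes would share 1408 higher and 1232 lower genes. Log2 fold changes correlated at 0.953 across genes, with a covariance of 3.13. In 50 simulations of unchanged groups set against the same H libraries these were 0.0921 and 0.00456, a covariance difference of 3.13. The simulated groups were drawn around the observed mean of H, so the error of that mean, which both comparisons share, was left out. The simulations therefore cannot show how much the shared H libraries add. With 3 H libraries the controls cannot be split into parts of at least 2, so part of the excess overlap may come from the shared libraries.

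On a scale where the mean of H is 0 and the mean of pC is 1, HpC lay at 0.902 ± 0.0787 (SD, n = 4) and left-out pC at 0.986 ± 0.0712 (n = 3). Single libraries lay at 0.810 in HpC1, 0.894 in HpC2, 0.901 in HpC3 and 1.003 in HpC4. The difference of -0.0846 was within the spread between libraries (exact permutation p = 0.286, two-sided; the smallest possible is 0.0286). The cholangiocyte identity score was 6.80 ± 0.294 in HpC and 7.04 ± 0.243 in pC, a difference of -0.24 (exact permutation p = 0.286; adjusted p = 0.534 over the list scores), against 1.20 ± 0.116 in H. A p that misses the threshold does not show that the groups are alike.

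**Figure D3:**
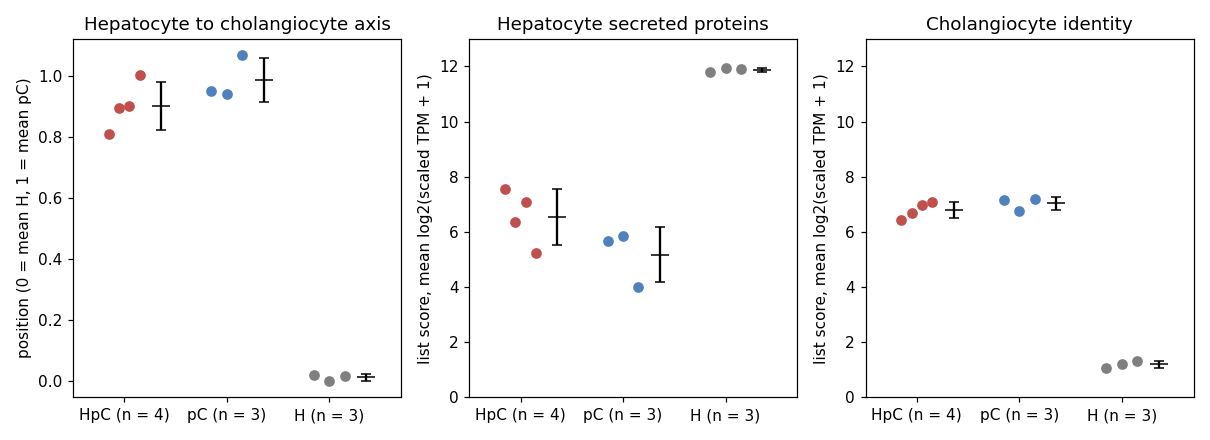
Position of each library between hepatocytes (0) and peripheral cholangiocytes (1), left, and list scores as mean log2(scaled TPM + 1) of 22 hepatocyte secreted protein genes, middle, and 19 cholangiocyte identity genes, right; points are libraries of HpC (red, n = 4), pC (blue, n = 3) and H (grey, n = 3), and black marks the mean and SD. HpC averaged 0.902 and pC 0.986 on the position scale, and their scores overlapped in both lists.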

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

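The tests of pancreatic and squamous RNA, of carry-over for the called hepatocyte genes and of all 3 explanations for antigen presentation were chosen only after the result was seen.

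Among 160 values with 4 HpC libraries, 7 had 1 library far from the other 3, with a gap to range ratio above Dixon's 95% limit; chance gives about 1 in 20. HpC1 stood apart in Lfng (0.980), high at 2.92 on the log2 scale, in Ezr, which encodes ezrin (0.832), low at 8.18, in the epithelial junction score (0.866), low at 6.11, and in the p53 and senescence score (0.845), low at 4.30. HpC2 stood apart in the cell cycle score (0.836), high at 3.40. HpC3 was low in the antiproliferative gene Btg2 (0.868), at 7.07, and HpC4 in Cyp2a5 (0.874), at 1.57.

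HpC1 held pancreatic transcripts and HpC2 those of squamous epithelium. RNA of pancreatic cells brings acinar regulators and secretory genes with the enzymes. Of 8 such genes 7 (87.5%) were over 10 times higher in HpC1 than in any other library. The regulators Ptf1a and Bhlha15 were among them, while the regulator Rbpjl, at 6.045 times the next library, was not. The same bound was met by 3 of 6 islet hormone genes, with Ins2 at 244 deposited TPM. RNA of squamous epithelium brings its regulators. Of 6 genes listed as such, which include the collagen gene Col17a1, 5 (83.3%) met that bound in HpC2, Trp63, Pitx1 and Sox2 among them. Both sources are consistent with tissue taken along or RNA carried over between samples, and pC3, with 0.203% of its TPM in pancreatic enzymes, and HpC3, with 0.0304%, may hold traces of the first. A change of identity within the sorted cells was not tested.

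Some hepatocyte genes were higher in HpC than in pC. RNA carried over from hepatocytes raises abundant genes by 1 share of their level in H; over 40 genes the excess in HpC had quartiles of 0.763% and 2.71% of H (ratio 3.54), too close to decide. For the 7 called list genes, the median excess was 1.78 times the median share of 35 other genes in HpC1, the lowest of the libraries, and 8.28 times in HpC4. These 7 were chosen as called higher in the same libraries, so a lead over genes that were not called is in part built in. In no HpC library did all 7 lie above the upper quartile of the others, so that carry-over and retained expression cannot be told apart. The bound on all 7 genes was made stricter after these values were seen; under the earlier one carry-over had been ruled out. Hepatocyte origin of HpC, which the design names, stays open and untested.

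Antigen presentation genes were lower in HpC. Macrophages in the pC sort would raise their markers there. The summed markers had an HpC to pC ratio of 0.968, against 0.0933 to 0.327 for the called genes. Variants of the histocompatibility locus on chromosome 17 in the mixed strains would leave genes elsewhere unmoved, but Cd74, Ciita and B2m had a median of -2.04. Of these Cd74 and Ciita were called lower and B2m was not (-0.90, limma adjusted p = 0.0546). This test does not cover the genes on chromosome 17, for which variants stay open. B cells or dendritic cells in the pC sort would bring their abundant markers, but 8 of these summed to 0.478 scaled TPM in pC and 1.09 in HpC (ratio 2.28), and the highest in pC, Siglech, stood at 0.191 beside an excess of 630 for Cd74. An earlier bound, which asked for markers at 1 scaled TPM, had left this explanation open. A change in the cholangiocytes stays open. Other cell types in the sorts may differ: 2 of 5 lists, stellate and mesothelial markers, had over 75% of members higher in HpC and passed camera at the preset correlation, but not with an estimated one (adjusted p = 0.710 and 0.151). Only 1 of 14 stellate and 3 of 7 mesothelial markers were called higher. Their summed levels were 111 against 81.5 and 44.1 against 27.8 scaled TPM. Genotype, which the design names, was not tested apart from cell origin.

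Chance is an unlikely source of the count of HpC against pC. Of 35 splits of the libraries 1, the real one, gave as many genes (671, highest other 24). With 35 splits that share cannot fall below 0.0286, so chance is not excluded. For HpC against H the real split also gave the most genes (1 of 35, 8842). The highest other count was 5279, with HpC1 placed among H. It was 4235 with HpC2 placed there, 1 with HpC3 and 0 with HpC4, and the cause was not tested. By the ages only HpC4 may share a mouse with H2 or H3, and H2 and H3 may share one. These splits may therefore not be of independent samples. For pC against H, 10 splits are too few (8806; highest other 1).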

How the results depend on the processing

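For calls of genes and lists, TPM as deposited, the other pseudocounts, array weights, the protein-coding set and the fit without HpC1 and HpC2 together were chosen after seeing the data, as was the overlap without HpC1.

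For HpC against pC the counts were 202 higher and 191 lower in only the libraries of both groups (393 of 14424 genes, with fewer libraries), 408 lower of 552 in all on TPM as deposited (so 1.4e+02 higher), 831 and 966 with array weights, and 316 and 243 without HpC1 and HpC2. Leaving out 1 library gave 138 to 364 higher and 133 to 447 lower, and 9 to 17 lists past 5% instead of 12; with the correlation estimated per list 1 was left. For HpC against H TPM as deposited gave 7553 and 1519, leaving out 1 library 3946 to 4854 and 3808 to 4287, and lists stayed at 24, or 0 with estimated correlations. For pC against H these were 9361 and 1255, 3931 to 5077, 3740 to 4263, and 22 to 24 lists, or 0. Apart from fewer libraries, and the scaling that TPM as deposited leaves out, the cause was not tested.

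Among named genes and lists, 1 gene and 1 list reversed their test direction with a call before or after. They were Onecut1 between pC and H, at 1.46 on TPM as deposited instead of -0.08, and the ribosomal list between HpC and pC, at -0.0182 without HpC1 and HpC2 instead of 0.47. The cause was not tested. Over all genes called both ways on TPM as deposited, 5844 of 6224 kept their direction for pC against H, 6039 of 6044 for HpC against H and 426 of 426 for HpC against pC. The respiratory chain list between HpC and pC kept its test direction on TPM as deposited, but its mean went from 0.29 to -0.13. Of 1276 values of named genes for HpC against pC under the alternatives, 1116 stayed on their side of the threshold, 36 gained a call and the rest lost it; for HpC against H 1424 of 1425 and for pC against H 1332 of 1338 stayed. Among values called in neither fit, the sign changed for 5 of named genes and 23 list means (HpC against pC), 7 list means (HpC against H), and 7 of named genes and 8 list means (pC against H). Of 38 named genes called between HpC and pC, 19 were called in every alternative, Ciita in all where it was tested, and 14 lost the call in some fit without 1 library. Some fits gave no value because genes missed the filter: Ciita without any single pC library, Lfng without HpC1 and HpC2, Notum without any single H library, Tek in 5 fits, and Tbx3, Ccl5, macrophage markers (HpC against H) and mesothelial markers (pC against H) in only the libraries of both groups.

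Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.0458 to 0.0839. With the replicate number as a block the counts were 269 and 304 (HpC against pC), 4161 and 4023 (HpC against H) and 4528 and 4169 (pC against H), with 17 lists past 5% for HpC against pC.

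Leaving out 1 HpC or pC library moved the position difference between -0.119 and -0.0539 and the hepatocyte score difference between 0.795 and 1.82. The cholangiocyte score difference moved between -0.384 and -0.121 (exact permutation p 0.1 or more for all of these). With 1 library left out, the splits are too few for that test to pass the threshold, whatever the values. These p-values therefore show neither a difference nor its absence. The overlap was 7754 without HpC1 and 5117 with changes of at least 2-fold. A count-model Wald test, voom with quality weights and an average-length offset were not run, for lack of counts and effective lengths. Depth is unknown, so no limit of detection can be set.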

Other observations

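The genes below were picked after their values were seen, by a rule of at least 5 scaled TPM in every library of a cholangiocyte group and under 1 in every library of the other. In HpC, 5 genes met it while also staying under 1 in every H library: Tbx1, a T-box transcription factor, at 18.2 ± 4.56 scaled TPM (SD, n = 4) against 0.275 ± 0.200 in pC (n = 3; 3.89 ± 0.22 on the log2 scale, SE, limma adjusted p = 2.44e-05), Lgr6, an R-spondin receptor and epithelial stem cell marker, at 28.6 ± 8.95 against 0.748 ± 0.165 (4.03 ± 0.23, adjusted p = 2.44e-05), Psca, prostate stem cell antigen, at 13.6 ± 3.11 against 0.178 ± 0.109 (3.60 ± 0.19, adjusted p = 2.44e-05), Tmeff2 at 10.1 ± 4.38 against 0.461 ± 0.136, and Loxl2, a lysyl oxidase that crosslinks collagen, at 6.60 ± 1.02 against 0.604 ± 0.104. Conversely, 2 genes were at 5 or more in every pC library and under 1 in every HpC library: Gal3st2, a galactose sulfotransferase (7.52 ± 1.73 in pC against 0.683 ± 0.180 in HpC; -2.33 ± 0.17, limma adjusted p = 0.000165), and the unnamed gene 4430402I18Rik (6.23 ± 1.42 against 0.820 ± 0.128; -1.98 ± 0.19, adjusted p = 0.000626), which stood at 3.88 in H. Of these, Gal3st2 missed the low-value filter without any single pC library, and Tbx1, Psca and Tmeff2 missed it without HpC1 and HpC2 together, so they were not tested there.

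Class I genes stood apart in pC2: H2-K1 was at 1355 scaled TPM there against 325 in pC1 and 466 in pC3, and H2-D1 at 1059 against 192 and 276. HpC2 also had the highest cell cycle score of all libraries, 3.40 against 1.67 to 2.15 in the other cholangiocyte libraries.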
